A study of Zea mays with 15 samples.

How the data were processed

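Transcripts were measured in 15 libraries of B73 maize leaves, 3 each at 0 h (water) and at 24, 40, 60 and 96 h after inoculation with the fungus. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with an Illumina messenger RNA kit of the TruSeq series. The aligner, the counting tool, the genome build and the strandedness are not given in the sources used here. The authors deposited a table of whole-number counts per gene, which is raw per the file headers and the values, with 46430 features. The authors also deposited an FPKM table (fragments scaled by gene length and by library total) with 46276 of these features, and the 154 others are microRNA precursors with 0 counts. The FPKM values equal the counts divided by a gene length and by the column total, to a largest relative deviation of 3.0e-07, so they carry the scaling of library totals and no further normalization. Every column matched 1 sample by its label, and 0 columns were left over. No pair of libraries held identical counts.

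Features were classed by identifier as 44146 nuclear gene models, 1765 non-coding RNA models, and genes of the chloroplast and the mitochondrion. Names came from the RefSeq gene table of assembly Zm-B73-REFERENCE-NAM-5.0. It matched the organelle genes and 153 microRNAs and 0 nuclear identifiers. No coordinates are printed because the build behind the deposited tables is not given in the sources used here. Consequently 29 gene lists fixed before the data were examined, among them NPF, NRT2, defence and photosynthesis lists, gained 0 nuclear members. Of these, 2 matched organelle genes only and were void, so the planned list tests and the NPF and NRT2 counts were not run. Reads from organelle genes and from their copies in the nuclear genome, from recent paralogs and from overlapping genes can be split or mixed by counting, so values of such genes are uncertain.

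Counts were tested with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood test (glmQLFit and glmQLFTest) with TMM factors, in 1 fit over all 15 libraries with a coefficient per time and no covariate. The filter filterByExpr kept 24855 features and removed 21575. P-values were adjusted by Benjamini-Hochberg within each comparison and called under 0.05 with no minimum fold. The common dispersion was 0.117, a biological coefficient of variation of 0.342. CPM in the text are scaled by TMM factors, except the number of genes reaching 1 CPM and shares of counts, which use library totals. TMM factors ran from 0.574 to 0.881 at 96 h and from 1.197 to 1.353 at 40 and 60 h. Where all libraries of a group had 0 counts, the fold was computed against a floor of 3 counts over that group, on the same TMM scale, and is a lower bound. With 1 to 3 counts in a group the ratio has an exact 95% interval from the counts. Intervals and floors cover counting error only, since reads were not tagged by molecule. Shares of counts were compared by exact permutation tests.

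The rule for named genes was fixed before the data were examined. For each time against 0 h it takes the 5 largest rises and 5 largest falls among called genes with a symbol, at least 10 CPM in the higher group and no overlap between libraries, and for each step 3 of each. Where identifiers have no symbol, it allows 2 that rose and 2 that fell. It named rrn18, rrn26 and ndhD among organelle genes, and others are marked where they appear.

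Alternatives were other scaling factors, filters, DESeq2 1.42.0, limma 3.58.1 on log2(FPKM + 1) and log2(FPKM + 0.1), a 2-fold minimum, a replicate block, fits of only the 2 groups compared, and leaving out each library. The 24 h group by 1 replicate alone and the count of mitochondrial genes were added after seeing the data. The tests were checked on simulated counts for the comparison of 24 h with 0 h, over 24855 genes of which 200 were changed. edgeR recovered 24% of genes changed 2-fold and 60% of those changed 4-fold, and 5.62% of its calls were false. limma on log2(FPKM + 1) recovered 28% and 63% with 5.21% false. DESeq2 recovered 46% and 78%, but 34% of its calls were false. In the simulation all other genes were equal at all times, whereas 14860 genes were called at 24 h in the data. These rates therefore hold for few changed genes and do not carry over to the real comparisons. The limit of 20% false calls was first set for all 3 tools; because DESeq2 exceeded it, the limit was then applied to edgeR alone. Other computations used Python 3.11.15 with scipy 1.17.1 and pandas 2.3.3.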

Results

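Messenger RNA of leaves of the maize inbred line B73, the line behind the maize reference genome, was sequenced before and during infection with Colletotrichum graminicola, the fungus that causes maize anthracnose. Leaves treated with water at 0 h were the control, and inoculated leaves were taken at 24, 40, 60 and 96 h. Each of the 5 times had 3 libraries, 15 in all, with total counts between 53036652 and 73146287 per library. The series title names the NPF and NRT2 families of nitrate transporters and their responses to pathogens. The reference table used here gave a name to 0 of the 44146 nuclear gene models, so these families were not analysed here, and nuclear genes are given by identifier. Named genes are those of the mitochondrion and the chloroplast. Each later time was compared with 0 h and with the time before it, to ask which transcripts change as infection proceeds. The only water control was taken at 0 h, so infection, leaf age and time of sampling change together in every comparison. No source says that the 3 libraries of a time came from separate plants, so the p-values measure the spread between these libraries, which may be technical.

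Most of the transcripts with enough counts to test changed during the 96 h. Of 24855 such genes, 22529 (90.6%) differed between times, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With TMM scaling, the changed genes peaked mainly at the ends of the course and at 24 h. Their mean was highest at 0 h for 5241 genes, at 24 h for 5002, at 40 h for 2426, at 60 h for 2323 and at 96 h for 7537. It was lowest at these times for 5067, 5457, 2029, 1993 and 7983 genes. These numbers rest on TMM factors, which were lowest at 96 h and highest at 40 and 60 h, and were not recomputed with other scaling. With library totals only, 23.9% of the genes changed from 60 to 96 h were higher, against 48.2% with TMM factors. The time of the highest mean may therefore depend on scaling. Fewer genes reached 1 CPM (a count scaled to the size of its library) at 96 h than at 0 h, 17669 ± 1009 against 19461 ± 352 (SD, n = 3, exact permutation p = 0.1, two-sided, the smallest that 3 against 3 libraries allow). Across genes, which are not independent replicates, the Spearman correlation with the 0 h libraries, averaged over the 9 pairs of libraries, was 0.827 at 24 h, 0.888 at 40 h, 0.850 at 60 h and 0.639 at 96 h. The first principal component held 52.5% of the variance and separated the 96 h libraries, at 246 to 346, from the other 12, at -167 to 6.02. The second held 20.2% and separated the 24 h libraries, at 180 to 194, from the rest, at -117 to 2.28.

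**Figure D1:**
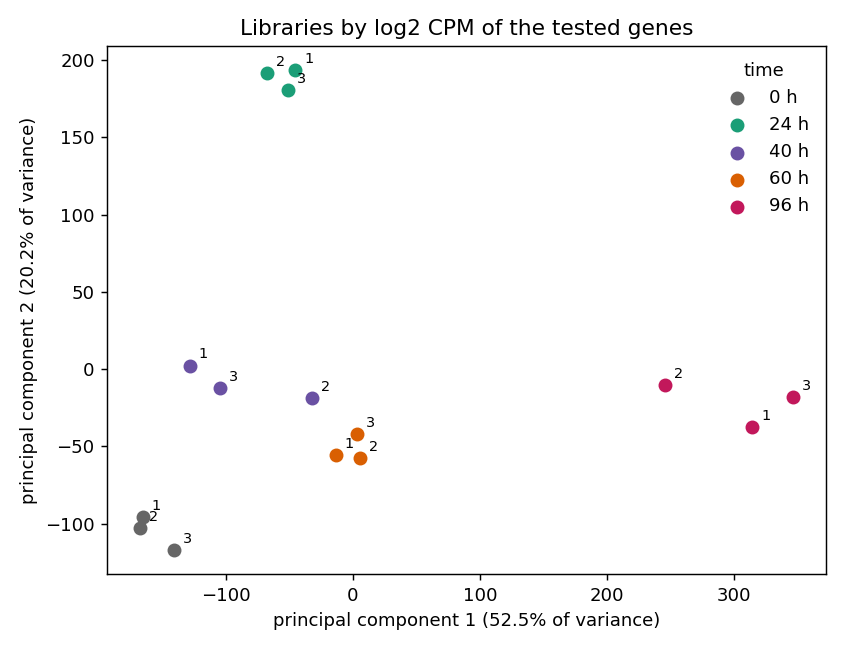
Principal components 1 and 2 (arbitrary units) of log2 CPM over the tested genes, with 1 point per library, coloured by time and numbered by replicate. The 96 h libraries stand apart on the first component and the 24 h libraries on the second, and replicate 2 of 40 h lies nearest to the 60 h libraries.

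At 24 h, nuclear transcripts had moved in both directions, and the most extreme changes were losses. Of the tested genes 14860 (59.8%) changed, 7222 higher and 7638 lower than at 0 h, and among them 739 were at least 16-fold higher and 1270 at least 16-fold lower (genes with 0 counts in a group set at their floor). The gene Zm00001d038696 had 0 counts in all 3 control libraries and 37.2 ± 5.75 CPM (SD, n = 3) at 24 h, at least 2340-fold higher against a floor of 3 counts over the control group. Likewise Zm00001d035558 rose from 0 to 31.4 ± 1.41 CPM, at least 1970-fold higher. In the other direction Zm00001d006446 fell from 193 ± 113 CPM to 0 counts, at least 11200-fold lower, and Zm00001d037383 from 172 ± 53.9 CPM to 0, at least 10000-fold lower. In all, 185 genes with 0 counts in the controls were called higher at 24 h, and 302 genes with 0 counts at 24 h were called lower. Both tested mitochondrial ribosomal RNA genes rose, rrn26 (large subunit) by 1.51 ± 0.36 (SE) on the log2 scale and rrn18 (small subunit) by 1.48 ± 0.42. Their adjusted p was 0.00267 and 0.00816 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and all 3 libraries of 24 h lay above all 3 controls for both genes. Of the 12 mitochondrial protein-coding genes tested 0 were called higher and 1 lower, rps2B, a ribosomal protein gene named after its values were seen, with 0 counts in all 3 libraries of 24 h against 18, 20 and 25 in the controls. ndhD, a chloroplast gene for a subunit of the NDH complex, was called higher by 3.72 ± 0.71 on the log2 scale, but its CPM was 14.1, 16.3 and 1.67 in replicates 1, 2 and 3, against 0.81 ± 0.463 in the controls. ndhA of the same complex, named after its values were seen, was called higher by 2.44 ± 0.92, with 147, 103 and 17 counts in these replicates against 29, 12 and 10 in the controls. With 24 h represented by replicate 3 alone, a choice made after seeing the data, the calls of these organelle genes were lost. The log2 fold change of ndhD dropped to 1.03 and that of ndhA to 0.20, while that of rrn26 was 1.37, near its value with 3 libraries. That of rps2B was -7.42, a fitted value and not a measured fold, since its count at 24 h was 0. rrn18 had 11.1 CPM in replicate 3. The call of rrn18 was also lost with replicate 2 alone, at a log2 fold change of 1.41, those of rps2B and ndhA with each replicate alone, and that of ndhA also without replicate 1 or replicate 2 of 24 h (2.04 and 2.18), without replicate 2 or replicate 3 of the controls (2.23 and 2.13) and with no count filter (2.45). The count of changed genes was 10224, 9694 and 9536 with replicate 1, 2 or 3 alone, each lone library being assumed to vary like the other groups.

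At 40 h, gains and losses were equal in number and fewer than at 24 h. Of the tested genes 9513 (38.3%) changed, 4757 higher and 4756 lower than at 0 h, with 538 at least 16-fold higher and 390 at least 16-fold lower. The largest rises were in genes with 0 counts in the controls: Zm00001d032858 reached 140 ± 176 CPM (SD, n = 3), at least 8780-fold higher, and Zm00001d031157 84.4 ± 114 CPM, at least 5300-fold higher. Replicate 2 carried much of both means, with 341 CPM for Zm00001d032858 against 12.1 and 66.1 in replicates 1 and 3, and 216 CPM for Zm00001d031157 against 7.75 and 29.5. Without it the bounds were 2460-fold and 1170-fold. In the other direction Zm00001d038476 fell from 56.5 ± 39.3 CPM (10610 counts over the 3 controls) to 1 count over the 3 libraries of 40 h, 12300-fold lower with a 95% counting interval of 2210 to 487000 (7570-fold without replicate 1 of the controls), and Zm00001d049111 went from 14.9 ± 5.03 CPM to 0 counts, at least 1090-fold lower. Non-coding RNA gene models were more often higher than lower, 18 against 6 of 167 tested, and their share of all counts was 0.0280% ± 0.00660 against 0.0181% ± 0.00186 at 0 h (n = 3, exact permutation p = 0.1, two-sided, the smallest possible). The 2 mitochondrial rRNA genes had a median log2 fold change of 0.66 at 40 h and the 4 tested chloroplast genes one of -1.32, without passing the threshold. With library totals only, both rRNA genes were called higher, with a median of 1.04, but neither was with RLE or upper-quartile factors. The equal numbers of rises and falls depend on scaling by TMM factors: with library totals only 72.9% of the changed genes were higher, and with limma on FPKM values 68.4% to 72.9% were.

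At 60 h, gains and losses were close in number, and the 2 genes with the largest rises at 40 h again had the largest rises. Of the tested genes 10902 (43.9%) changed, 5662 higher and 5240 lower than at 0 h, with 783 at least 16-fold higher and 569 at least 16-fold lower. Zm00001d032858 stood at 199 ± 27.2 CPM (SD, n = 3) against 0 counts at 0 h, at least 12500-fold higher, and Zm00001d031157 at 129 ± 23.0 CPM, at least 8130-fold higher. Zm00001d029913 fell from 67.5 ± 22.4 CPM to 0 counts, at least 5170-fold lower, and Zm00001d038476 again had 1 count over the 3 libraries, 12900-fold lower (95% counting interval 2320 to 511000), or 7930-fold without replicate 1 of the controls. The mitochondrial rRNA gene rrn18 was 13.7 ± 1.86 CPM against 5.48 ± 0.537 at 0 h, a log2 fold change of 1.32 ± 0.42 (adjusted p = 0.0205, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, higher in 3 of 3 libraries). The other, rrn26, was not called, with 0.72 ± 0.35 (adjusted p = 0.115 in the same edgeR test with Benjamini-Hochberg adjustment), but was called with library totals only (1.11), with limma on FPKM values (1.01 to 1.09) and in the fit of the 2 groups alone (0.71). Of the 4 chloroplast genes tested 1 was called, matK, a maturase gene named after its values were seen, lower by 2.71 ± 0.63. Non-coding RNA models were higher for 27 and lower for 8 of 167, while their share of all counts was 0.0178% ± 0.00205 against 0.0181% ± 0.00186 at 0 h (n = 3, exact permutation p = 0.9, two-sided). The call of rrn18 was lost in 5 of the 6 fits that left out 1 library of the 2 groups (adjusted p 0.0551 to 0.0734 in the same edgeR test with Benjamini-Hochberg adjustment), while its log2 fold change stayed between 1.21 and 1.35 in these 5. Which direction was more frequent depended on the processing: 51.9% of the changed genes were higher with TMM factors, 47.1% with RLE factors and 47.2% with DESeq2, but 71.4% with library totals only and 68.0% to 72.6% with limma on FPKM values.

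At 96 h, most of the tested genes had changed, and mitochondrial transcripts were among those that rose. Of the tested genes 18089 (72.8%) changed, 8917 higher and 9172 lower than at 0 h, with 1992 at least 16-fold higher and 2175 at least 16-fold lower. The mitochondrial rRNA gene rrn18 rose from 5.48 ± 0.537 to 535 ± 322 CPM (SD, n = 3) and rrn26 from 28.3 ± 1.70 to 754 ± 426 CPM. Their log2 fold changes were 6.61 ± 0.52 and 4.74 ± 0.41 (SE), with adjusted p of 1.65e-07 and 3.6e-07 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and all 3 libraries of 96 h lay above all 3 controls. Replicate 2 was lowest at 96 h, with 164 CPM against 696 and 745 for rrn18, and 267 CPM against 942 and 1050 for rrn26. Mitochondrial protein-coding genes rose as well: 10 of 12 tested were called higher, with a median log2 fold change of 4.11. Among them, named after their values were seen, cox1, a subunit gene of cytochrome c oxidase, rose by 4.82 ± 0.75 on the log2 scale from 0.158 to 4.54 CPM, and atp4, an ATP synthase subunit gene, by 5.04 ± 0.95 from 0.0624 to 2.14 CPM. The 2 that were not called, orf101-a and rps2B, had log2 fold changes of 0.50 ± 0.95 and 0.25 ± 0.96. Some of the 12 genes passed the filter only through their 96 h counts. Of these, nad4 had 49, 17 and 34 counts at 96 h and 0 to 9 elsewhere, and rps7 had 21, 16 and 18 against 0 to 3. The share of genes called higher and their median are therefore partly set by the filter. Of the calls, that of rps1 (3.01) was lost with library totals only (2.57), no count filter, the replicate block and any library of the 2 groups left out. That of orf140-b (3.79) was lost with library totals only (3.27), no count filter, and without replicate 1 or 3 of 96 h or replicate 2 or 3 of the controls. Chloroplast genes moved the other way: matK, ndhD and ndhA, also named after their values were seen, fell, with log2 fold changes of -2.65 ± 0.64, -2.35 ± 0.76 and -2.96 ± 1.12, and atpA had -2.74 ± 1.33 and was not called. The call of ndhD was lost with limma on log2(FPKM + 1), filtered or not (log2 fold change -0.47 in both). That of ndhA was lost with the latter unfiltered (-0.28), with the replicate block (-2.79), in the fit of the 2 groups alone (-3.03), and without replicate 1 of 96 h (-2.48), replicate 2 of 96 h (-2.37) or replicate 1 of the controls (-2.39). These directions for both organelles held with RLE, upper-quartile and no scaling factors, with 8 to 10 of the 12 mitochondrial protein-coding genes called.

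Among nuclear genes at 96 h, Zm00001d007631 went from 0 counts in the controls to 1630 ± 1080 CPM (SD, n = 3), at least 103000-fold higher, and Zm00001d043350 to 1160 ± 896 CPM, at least 72600-fold higher. Replicate 3 weighed on both means, and without it the bounds were 67500-fold and 45700-fold. Replicate 2 was lowest for both, at 609 CPM against 1530 and 2760 for Zm00001d007631, and at 224 CPM against 1230 and 2010 for Zm00001d043350. Zm00001d037513 went from 1880 ± 147 CPM to 0 counts in all 3 libraries, at least 79300-fold lower, and Zm00001d027291 from 415 ± 164 CPM to 0, at least 17500-fold lower. Genes with 0 counts in the controls and called higher numbered 344, of which 212 reached a mean of 1 CPM, and 522 genes with 0 counts at 96 h were called lower. Non-coding RNA models fell far more often than they rose, 59 against 8 of 167, and their share of all counts was 0.00328% ± 0.00102 against 0.0181% ± 0.00186 at 0 h (n = 3, exact permutation p = 0.1, two-sided, the smallest possible). Rises and falls were about equal in number with TMM factors (49.3% higher), while 39.2% of the changed genes were higher with library totals only and 38.3% to 39.0% with limma on FPKM values. With library totals only, the median log2 fold change of all tested genes was 0.43 at 40 h, 0.43 at 60 h and -0.48 at 96 h, against 0.04, 0.05 and -0.07 with TMM factors, so the directions given here are relative to TMM scaling.

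**Figure D2:**
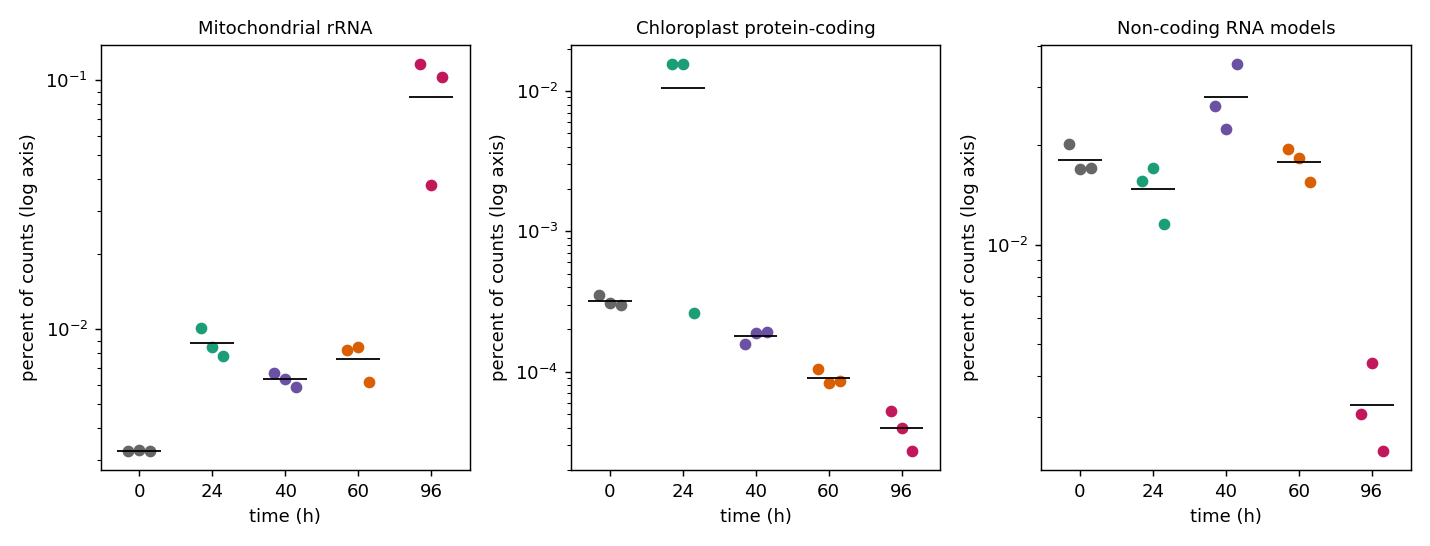
Percent of each library's counts (log axis) on mitochondrial rRNA, chloroplast protein-coding genes and non-coding RNA models against time in hours, with 1 point per library and a line at the mean of the 3. Mitochondrial rRNA rises from 0.00326% at 0 h to a mean of 0.0858% at 96 h, and the chloroplast share is near 0.0155% in 24 h replicates 1 and 2 and 0.000263% in replicate 3.

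From 24 to 40 h, 12217 genes changed, 6433 higher and 5784 lower at 40 h. ndhD was lower at 40 h by 4.36 ± 0.74 (SE) on the log2 scale, a call that was lost with 24 h by replicate 3 alone (log2 fold change -1.67). ndhA was lower by 3.78 ± 0.98, lost in the same way (-1.55). rps2B was called higher, with 0 counts in all 3 libraries of 24 h and 0, 14 and 2 counts at 40 h. Its fitted log2 fold change of 5.21 ± 1.77 is therefore not a measured fold, and was 2.97 without replicate 2 of 40 h. The call of rps2B was lost in 9 alternatives, among them the leaving out of any 24 h library. rrn26 was lower, going from 80.8 ± 8.69 to 40.5 ± 3.43 CPM (SD, n = 3), and its call was lost with library totals only (log2 fold change -0.54) and with each 24 h or 40 h library left out. Non-coding RNA models were higher at 40 h for 25 and lower for 2 of 167. With 24 h by replicate 1, 2 or 3 alone the count was 6640, 6898 and 5632 genes. With library totals only 75.2% of the changed genes were higher, with upper-quartile factors 64.7% and with limma on FPKM values 70.7% to 72.8%, against 52.7% with TMM factors.

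The step from 40 to 60 h changed the fewest genes of the 3 steps, 2505, of which 1207 were higher and 1298 lower at 60 h. The mitochondrial rRNA genes had a median log2 fold change of 0.36 and the 12 mitochondrial protein-coding genes one of 0.76, without passing the threshold. Of 167 non-coding RNA models 1 was called, lower at 60 h. This count depended on replicate 2 of 40 h: 4933 genes were called without it, and between 1127 and 1486 when any other library of the 2 groups was left out. DESeq2 called 4054 genes and limma on log2(FPKM + 1) 3821.

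From 60 to 96 h, 16420 genes changed, 7919 higher and 8501 lower at 96 h. The mitochondrial rRNA genes rose, rrn18 by 5.29 ± 0.49 (SE) on the log2 scale from 13.7 ± 1.86 to 535 ± 322 CPM (SD, n = 3), and rrn26 by 4.01 ± 0.40 from 46.8 ± 7.58 to 754 ± 426 CPM. Of the 12 mitochondrial protein-coding genes, some of which passed the filter only through their 96 h counts, 8 were called higher. The median log2 fold change of the 12 was 2.87. The call of cox3 was lost in 8 alternatives, among them library totals only (log2 fold change 1.23). That of nad4 was lost without replicate 2 of 60 h (3.15). Non-coding RNA models were lower at 96 h for 75 and higher for 4 of 167. With library totals only 23.9% of the changed genes were higher, and with limma on FPKM values 23.5% to 25.8%, against 48.2% with TMM factors. With library totals only, 249 of the 16420 genes were called in the opposite direction.

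**Figure D3:**
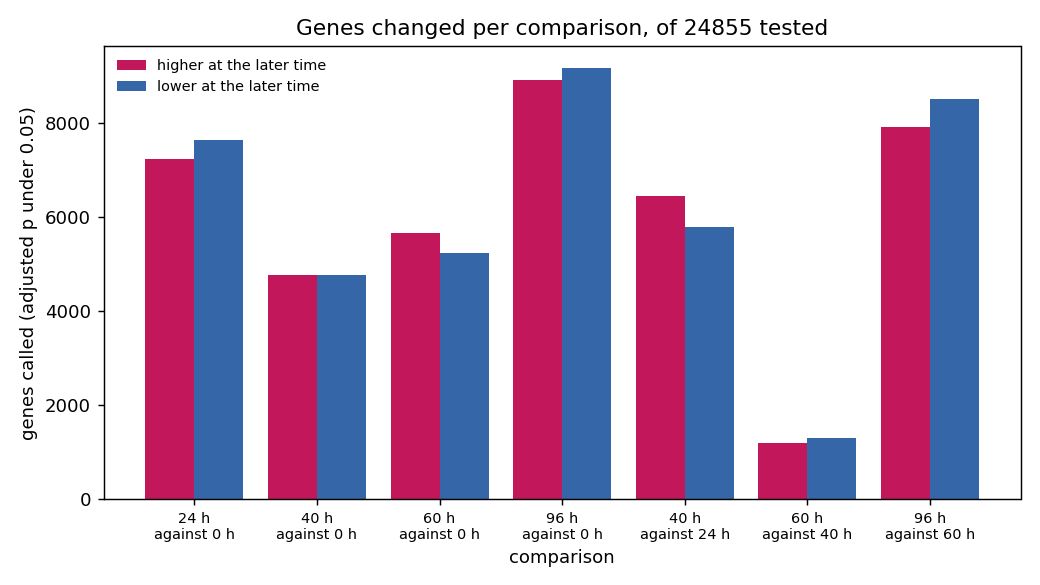
Number of genes called higher (red) or lower (blue) at the later time in each of the 7 comparisons, of 24855 tested (adjusted p under 0.05, edgeR). The bars are tallest for 96 h against 0 h (8917 and 9172) and shortest for 60 h against 40 h (1207 and 1298).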

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

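All tests of explanations in this part were chosen after the result was seen, except the comparison of odd libraries within the 24 h group.

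Chloroplast-encoded genes, most of which did not pass the filter of the tests, stood out in replicates 1 and 2 of 24 h. They took 0.01552% of the counts in replicate 1 and 0.01558% in replicate 2, against 0.000300% to 0.000352% in the 3 controls and 0.000263% in replicate 3. The same pair held 145 features (among them 100 nuclear, 35 of the chloroplast and 8 non-coding) with at least 20 counts in both libraries and at most 3 counts over the other 13, and the next pair of libraries held 6. Chosen for near absence from the other 13 libraries, these features could not pass the filter of the tests, and 0 of them enter the counts of changed genes. Tested genes with a like excess do enter them. ndhD, with 944, 876 and 90 counts in replicates 1, 2 and 3, and ndhA, with 147, 103 and 17, were called at 24 h.

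Depth is not the source of these features, since replicate 2 had 0.987 times the total count of replicate 3. A library batch, such as other DNA or RNA carried into 2 of the 3 libraries, may be the source. Outside these features, replicate 3 was the odd library (8-fold from both others, which lay within 2-fold of each other) at 109 nuclear genes, against 4 for replicate 1 and 13 for replicate 2. At 99 of the 109 it was the lower one, as in these features, so the count may reflect the same pattern and is not separate support. The measure of odd libraries is also not specific, since replicate 1 of 96 h was the odd library at 335 genes and replicate 3 of 0 h at 78. A difference between leaves stays open and was not tested, and the labels name no batch.

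Mitochondrial transcripts rose at 96 h while 3 of the 4 tested chloroplast genes were called lower, on few counts. Reads of fungal ribosomal RNA counted on maize genes could raise rrn18 and rrn26, whose median log2 fold change was 5.67, gene counts cannot separate this, and fungal reads on the 12 protein-coding genes were not tested. The tables argue against TMM scaling, since 10 of the 14 genes were called with library totals only. More RNA without poly(A) tails in the 96 h libraries stays open. The 4 chloroplast genes had a median of -2.70 and 3 were called lower, though ndhD and ndhA lost that call under some alternatives. They cannot decide this, since their fall is part of the pattern and few counts were left at 96 h: 4, 9 and 7 for ndhD, 0, 0 and 4 for ndhA, and 2, 1 and 0 for atpA. Infection and leaf age stay open and were not tested against each other.

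Many genes were called in opposite directions from 0 h at 2 different times. The difference between the 2 times was called in edgeR for all of them, which adds no support, since they were chosen for opposite calls. Higher at 24 h and lower at 96 h were 1424 genes, and lower at 24 h and higher at 96 h 1312. Between 24 and 40 h the numbers were 338 and 231, and between 24 and 60 h 521 and 572. Between 40 and 60 h they were 39 and 54, between 40 and 96 h 985 and 751, and between 60 and 96 h 638 and 525. The first number of each pair counts genes higher at the earlier time. The shared controls push the folds of 2 times the same way, not in opposite directions.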

How the results depend on the processing

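The 24 h group by 1 replicate alone and the count of mitochondrial genes were chosen after seeing the data. Of 161 recomputed counts of changed genes, 148 stayed within 1.5 times the reported value. The others were all in 3 comparisons. At 24 h against 0 h the count went from 14860 to 9694 with replicate 2 alone and 9536 with replicate 3 alone. At 40 h against 24 h it went from 12217 to 6640, 6898 and 5632 with replicates 1, 2 and 3 alone. All these rest on fewer samples, and of the 14860 genes 9376 were also called with replicate 3 alone. At 60 h against 40 h it went from 2505 to 4054 with DESeq2 and 3821 with limma on log2(FPKM + 1), and the cause was not tested. Leaving out 1 library gave 1127 to 4933 there, the highest without replicate 2 of 40 h. The same gave 13139 to 13836 at 24 h, 6888 to 8586 at 40 h, 8609 to 9450 at 60 h and 17013 to 18704 at 96 h against 0 h, 9983 to 11182 from 24 to 40 h, 14787 to 17005 from 60 to 96 h, and 22184 to 23217 over time. Mitochondrial genes called at 96 h were 12 of 14 tested, and 10 to 13 with a library left out, where 18 to 20 were tested. They were 3 with CPM of at least 1 in 3 libraries, 7 with limma on log2(FPKM + 1) and 7 on log2(FPKM + 0.1), where fewer genes passed the filter. Without the filter 76 were tested, and 14 were called with edgeR, 17 with DESeq2 and 19 with limma on log2(FPKM + 1). The share of 12 of 14 therefore depends on the filter.

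Of 983 recomputed values of named genes 899 kept their direction and side of the threshold, 78 lost the call, 6 gained it and no direction turned. The calls lost were those of rrn18, rrn26, ndhD, ndhA, rps1, rps2B, cox3, nad4 and orf140-b. The replicate numbers did not pair the libraries: same-numbered libraries correlated between -0.34 and 0.21 in their deviations from group means, and 2 of 15 were closest to their own number. With the replicate block the counts were 14408, 8689, 10313 and 17863 at 24, 40, 60 and 96 h against 0 h, 11455, 2051 and 16030 for the 3 steps, and 22174 over time, and 11 mitochondrial genes were called. The alternatives of the NPF and NRT2 counts and of the list tests were not run. The filter on low counts kept 4 chloroplast and 14 mitochondrial genes, and the others were not tested. Some chloroplast genes failed it because their counts lay in 2 libraries only. For example, ycf3 had 1214 and 1019 counts in replicates 1 and 2 of 24 h and 0 in every other library.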

Other observations

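In this part the effects of scaling and of the 24 h replicates were fixed before their results were seen, and the other tests were chosen after.

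In some of the tested genes the 24 and 96 h libraries stood together, apart from the other times. Across all tested genes the 2 times were not alike: the mean Spearman correlation of 24 h was 0.897 with 40 h and 0.718 with 96 h. They also held many opposite calls from 0 h, 1424 and 1312 genes. Each stood apart alone as well, 24 h at 5788 genes and 96 h at 10262. In 4295 of the 24855 tested genes all 6 libraries of 24 and 96 h lay on one side of all 9 libraries of 0, 40 and 60 h, 2273 above and 2022 below (326 and 482 of these by more than 2-fold). Chance gives 0.04% of genes for a pair only if all 15 libraries are exchangeable. Replicates of a time are alike, so that figure is no measure here, and even the lowest pair, 40 and 96 h, had 144 genes. The count of 24 and 96 h was the highest of the 10 pairs of times, ahead of 0 and 96 h (2123). Scaling does not account for it, since 4383 genes did so with library totals, again the highest of the 10 pairs. With 24 h by replicate 3 alone 5069 genes did so, also the highest of the 10 pairs. Leaving out libraries can only raise such a count, so the rise to 5069 says nothing about the doubted libraries. Only the rank could have changed, and it did not. If all leaves were inoculated together, 0, 24 and 96 h share an hour of day. A daily rhythm alone that acts alike at 40 and 60 h would then set that pair apart most often. It was set apart at 1481 genes, or 2823 with library totals, fewer than for 24 and 96 h in both cases. These counts cannot decide on a part of the hour of day in infected leaves, since 24 and 96 h would share both that hour and the inoculation. A candidate explanation is a stage of infection or a leaf response that recurs, which was not tested, since no mock-treated leaves of 24 or 96 h are among the samples used here.

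Genes with consecutive identifier numbers changed alike more than by chance. Over 13415 such pairs, Pearson's r of the log2 fold changes against 0 h was 0.166 at 24 h, 0.151 at 40 h, 0.152 at 60 h and 0.156 at 96 h. Shuffled pairs gave at most 0.027 (permutation p = 0.001, the smallest that 1000 shuffles can give). The pairs are genes, not independent replicates, and reads shared by adjacent copies were not tested.

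Replicate 2 of 40 h correlated with the 60 h libraries at 0.966 to 0.969 (Spearman, across genes) and with its own group at 0.940 and 0.962.

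For the number of changed genes, 3 against 3 libraries make 10 splits, too few for a share under 0.05. In each of the 7 comparisons 1 of the 10 splits, the real one, gave as many genes. The real values ran from 2505 to 18089, and the highest other split gave 3 genes at 40 h against 0 h and 0 in the other 6 comparisons. Over time, 1 of 100 splits gave as many genes, the real one with 22529, and the highest other gave 8138. The real split is among the 100, so the share cannot go below 1 in 100. Mixing times within a group also widens its spread, which lowers the calls of the other splits. The result argues against a random grouping of these libraries. It does not separate infection from technical differences between times, since the libraries of a time may be technical.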
